A study of Arabidopsis thaliana with 4 samples.

How the data were processed

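RNA abundance was measured on 4 spotted oligonucleotide arrays with 2 channels each, which set inflorescences of the Arabidopsis thaliana mutant pistillata directly against wild-type inflorescences. The 4 arrays form 1 group, the comparison of pistillata with wild type, and are called arrays 1 to 4 by the set numbers in the labels. The dyes are not given in the sources used here.

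The table the authors deposited holds log2 ratios of the channels of each array. Per the labels, these log2 values were processed and normalized as in an earlier publication, and the background correction, the normalization, the numerator and the handling of extreme values are not given in the sources used here. The values stop at 6.64 on either side of 0, the log2 of 100, so ratios beyond 100 in either direction have only a bound. The scale was read from those caps. The median log2 ratio of main-set gene probes as deposited was -0.12 on array 1, 0.14 on array 2, 0.11 on array 3 and -0.08 on array 4, so the centring of the columns also stays unknown. No signal strengths come with the ratios, so a probe's level above background is unknown.

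Of 26933 rows, 459 were left out, 424 as empty spots and 35 as control spots. The 26474 gene probes comprise 26090 of the main set and 384 of an additional set. Gene names came from the platform annotation supplied for this work, in which 5784 gene probes list 1 gene, 7497 list several and 13193 list none. Only probes with 1 gene were named, which gave 5443 genes; 5415 of these matched the reference gene table (assembly TAIR10.1) by gene number, and its symbols were used for them. No genome build is named for the array, so no coordinates are printed and the table served only for names and for which genes are neighbours. A gene with several probes was represented by the mean of their log ratios. Of 281 such genes tested, 28 had some but not all probes called, 1 had probes called in opposite directions and 40 had probe means over 1 log2 unit apart. A probe entered the tests with values on all 4 arrays, which 26156 gene probes had, and 5386 genes were tested. A value at a cap occurred on 1334 gene probes.

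The plan was to turn arrays 2 and 4 where the columns ran by the labels' channel order, or none where they already ran the same way. The ratios showed neither, so each array's sign was set by the anther genes TUA1, SHT, ATA20 and SWEET8, whose lists had been fixed as the guide to the common sign. Arrays 1 and 4 were multiplied by -1. The result is called the likely direction, and turning by the labels' channel order is given as an alternative chosen after the data were examined.

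Changes were tested with limma version 3.58.1 in R version 4.3.3, by lmFit with an intercept over the 4 turned ratios followed by eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes or over all probes and a threshold of 0.05. At least 2-fold means a mean log2 ratio of at least 1 in size. No further scaling was applied. Gene lists and families with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists or over the families, with an estimated correlation as an alternative and fry as a test of the members alone. Planned families needed at least 8 members. The plan was to define them by words in gene descriptions, but the words were sought only in the gene table's symbols and synonyms. Families by shared opening letters of the symbols and planned families of fewer members were added after the data were examined. A family by opening letters is not reported here.

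The lists, the named-gene rule, the tests and most other settings were fixed before the data were examined. The lists were floral organ identity and flower meristem regulators, tapetum and pollen wall, mature pollen and pollen tube, early anther patterning, meiosis, stamen maturation and jasmonate, petal and floral scent, carpel and ovule, photosynthesis, flavonoid pathway, cell division, and reference genes. GRP16 and EXL5 were left out of the tapetum list because the gene table gives their symbols to other loci. The rule names PISTILLATA, APETALA3 and AGAMOUS where measured, the 8 genes with the largest change in each direction among those past the threshold with the same sign on all 4 arrays, the 2 largest called changes in each direction of each list, and the measured genes of the organ identity and carpel lists. A few other members of lists and the direction genes are named with their values, chosen after these were seen.

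Alternatives were centring each array on its median, centring and scaling to the same spread, values on at least 3 arrays, a term for channel orientation, averaging arrays 1 and 2 and arrays 3 and 4 first, the same pairs as a random block, trended and robust variance moderation, array weights, an adjusted p of 0.01 and leaving out each array. Leaving out probes with a value at a cap, genes with 1 probe only, and turning by the labels' channel order were added after the data were examined. A filter on dim probes was planned only for a table with signals and was not run. For the same lack of signals, the trend in the variance moderation ran over the mean log ratio under test.

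The fit was tested on simulated data for the comparison of pistillata with wild type, with 200 of 5386 genes changed. It recovered 51 of 100 genes changed by 1 log2 unit and 86 of 100 changed by 3 log2 units, and called 4 unchanged genes. The prior degrees of freedom of eBayes on the real genes were 1.83. Tables and plots were made with Python version 3.11.15, pandas version 2.3.3, numpy version 2.4.6 and matplotlib version 3.10.9.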

Results

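Inflorescences of the Arabidopsis thaliana mutant pistillata were compared with wild-type inflorescences. PISTILLATA is a MADS-box transcription factor of the B class of floral organ identity genes, and flowers without it form no petals and no stamens. Total RNA from inflorescences, the flower-bearing shoot tips, was hybridised to 4 arrays of spotted long oligonucleotides. Each array carried pistillata RNA in one channel and wild-type RNA in the other, so every value is a ratio of the genotypes within an array. The labels put pistillata RNA in channel 1 of arrays 1 and 3 and in channel 2 of arrays 2 and 4. No label says that the 4 arrays hold separately grown samples, so the p-values measure the spread between these arrays, which may be technical. The number of arrays, 4, limits the precision, and no signal strengths or read depths belong to these values.

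The deposited table held log2 ratios for 26474 gene probes. Of these, 5784 listed 1 gene, 7497 listed several and 13193 listed none in the annotation used here. Genes are named only from probes that list 1 gene, which left 5386 genes with a value on all 4 arrays. PISTILLATA, its partner APETALA3 and AGAMOUS had no probe of their own in that annotation and are not analysed here, so the mutated gene could not serve as a check of the labels.

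The direction of the ratios came first, because a log2 ratio has a sign only once its numerator is known. Genes of the anther, the pollen-bearing part of the stamen, have transcripts in wild-type flowers and lack their tissue in pistillata. A set of 4 such genes from the lists fixed beforehand had a probe of its own: SWEET8, a sugar transporter needed for the pollen wall, SHT, a spermidine acyltransferase of the tapetum, ATA20, an anther-specific protein, and TUA1, an alpha-tubulin of pollen. Before any array was turned, their median log2 ratio was 2.91 on array 1, -2.77 on array 2, -3.15 on array 3 and 3.72 on array 4. All 4 genes had the same sign within each array. Arrays 1 and 4 therefore ran against arrays 2 and 3, whereas the channel order in the labels sets arrays 1 and 3 against arrays 2 and 4.

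**Figure D1:**
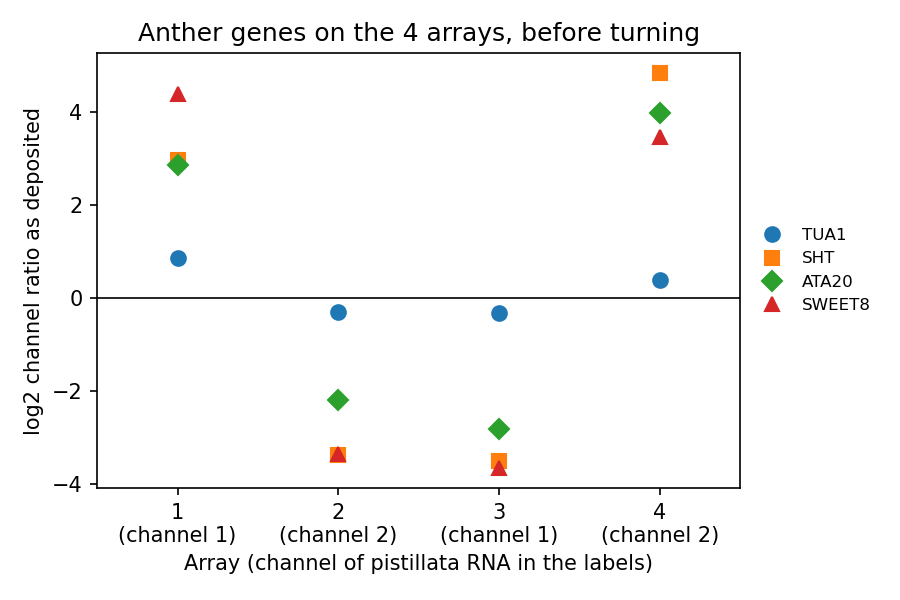
Log2 channel ratio as deposited (vertical axis) of the 4 anther genes on each array (horizontal axis, with the channel the labels give to pistillata RNA); every point is 1 gene on 1 array. All 4 genes lie above 0 on arrays 1 and 4 and below 0 on arrays 2 and 3.

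The same opposition was present across 25018 gene probes with no value at the caps of the table. Pearson's r was -0.68 between arrays 1 and 3 and -0.68 between arrays 2 and 4, the pairs with the same labelled channel order. It was 0.71 between arrays 1 and 4 and 0.77 between arrays 2 and 3, and these are correlations across probes, which are not independent replicates. Over all 26156 probes with 4 values, capped ones included, r was -0.30 for arrays 1 and 2, -0.29 for arrays 1 and 3, -0.05 for arrays 2 and 4 and 0.0057 for arrays 3 and 4, so the last pair showed no opposition by r. Spearman's rho for these pairs was -0.44, -0.39, -0.33 and -0.27. The labels therefore do not settle the direction. The ratios below are log2 of pistillata over wild type in the likely direction, with each array's sign set so that the anther genes lie on the wild-type side, and all p-values take that turning as given. With the common sign of all arrays exchanged, every lower count below would be a higher count and the reverse.

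Many transcripts were far less abundant in pistillata inflorescences. SWEET9, the sugar transporter through which nectaries secrete nectar, was 29.5-fold lower, at a log2 ratio of -4.88 ± 0.44 (SD, n = 4), with an adjusted p of 0.00112 by limma. AT1G66850, a member of the lipid transfer protein family measured by 3 probes, was 37.3-fold lower, at -5.22 ± 0.74 (SD, n = 4; limma adjusted p = 0.00223). AT5G07600, of the oleosin family, fell to -4.73 ± 1.06 and AT1G06260, of the papain-like cysteine protease family, to -4.88 ± 0.65 (SD, n = 4 each; limma adjusted p = 0.00583 and 0.00219). The lowest ratio among called genes with the same sign on all 4 arrays was that of AT3G01250, which was 62.4-fold lower at -5.96 ± 0.55 (SD, n = 4; limma adjusted p = 0.00112). AT3G52620, AT3G26860 and AT1G28375 completed the 8 lowest, with log2 ratios of -5.21, -5.10 and -4.75 and SDs of 0.74, 0.36 and 1.01 (n = 4 each).

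Increases were smaller. AT4G00910 was 4.51-fold higher in pistillata, at a log2 ratio of 2.17 ± 0.12 (SD, n = 4; limma adjusted p = 0.00153), and AT1G72290, of the Kunitz protease inhibitor family, was 4.13-fold higher at 2.05 ± 0.25 (SD, n = 4; limma adjusted p = 0.00246). GRI, which encodes the precursor of an extracellular cell-death peptide, stood at 1.97 ± 0.55 and AT5G45910, of the GDSL lipase family, at 1.91 ± 0.60 (SD, n = 4 each; limma adjusted p = 0.0125 and 0.0171). The adjusted p of GRI was 0.0559 without array 2 and 0.0568 without array 3, and that of AT5G45910 was 0.0559, 0.0818 and 0.0851 without arrays 2, 3 and 4. AT5G38900, AT5G53710, AT4G00920 and AT3G12000 rose by log2 ratios of 1.84, 1.82, 1.82 and 1.81, with SDs of 0.37, 0.33, 0.19 and 0.18 (n = 4 each). With trended and robust variance moderation in limma none of these 8 higher genes, and 0 genes in all, passed as higher. Without signals, that trend ran over the mean log ratio itself. Its variance thus depended on the size and sign of the change, so that fit cannot decide whether the higher calls hold. The value of AT5G53710 on array 2 was 2.31, apart from its 3 others.

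**Figure D2:**
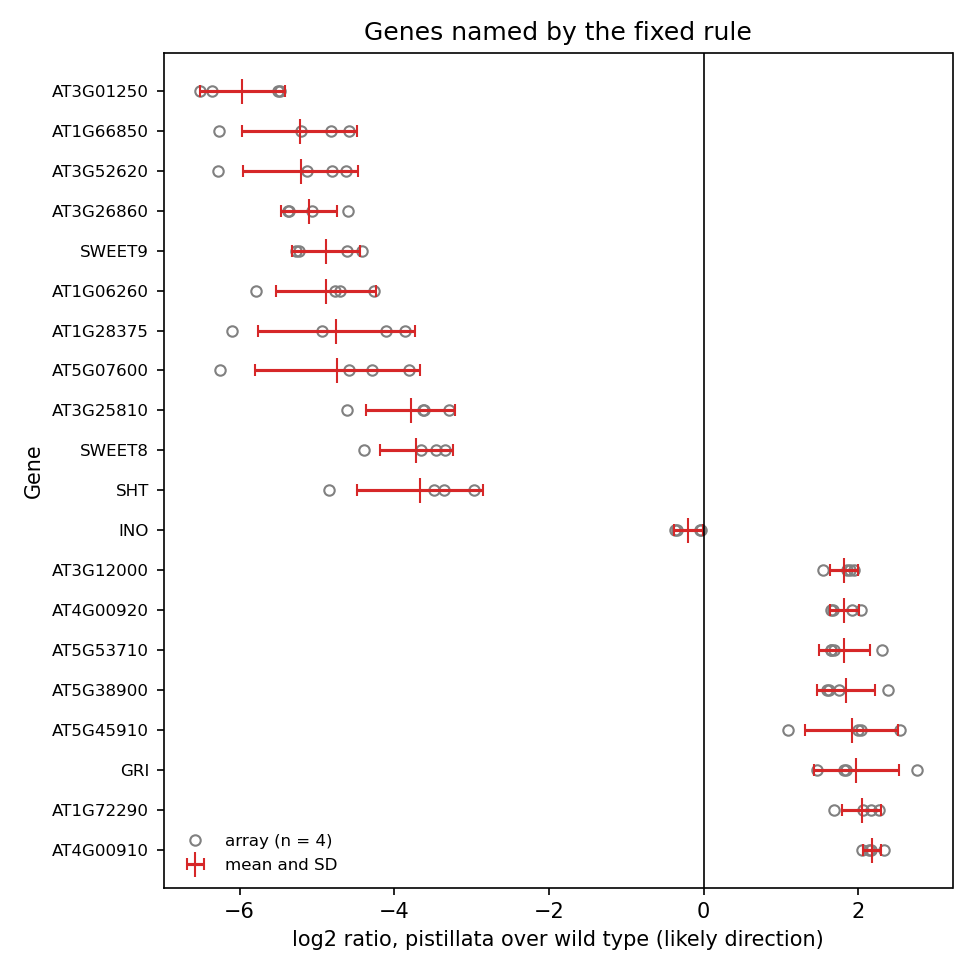
Log2 ratio of pistillata over wild type in the likely direction (horizontal axis) for the 20 genes named by the fixed rule (vertical axis); circles are the 4 arrays, and red marks give the mean and SD. Lower genes reach -5.96 for AT3G01250, higher genes reach 2.17 for AT4G00910, and INO lies at -0.20.

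In all, 460 of the 5386 genes passed an adjusted p of 0.05 by limma, 312 of them lower and 148 higher in pistillata. Of the genes that also changed at least 2-fold, 250 were lower and 30 higher. Each of the 460 had the same sign on all 4 arrays, which a test of the mean over the same arrays favours. At an unadjusted p under 0.05 there were 1661 genes, and there the balance was the other way, with 567 lower and 1094 higher. Over single probes, named or not, 1890 of 26156 were lower and 779 higher by limma. The share of called genes that were lower was 67.8% without further centring and 82.0% after each array was centred on its median, which moved the median of all genes from 0.16 to 0.05; genes higher then numbered 77 and genes lower 350. With arrays 1 and 2 and arrays 3 and 4 as a random block, higher genes outnumbered lower ones, 601 against 446 (42.6% lower). Over all probes after turning, r was 0.30 and -0.0057 in these pairs, against 0.49 for arrays 1 and 4 and 0.65 for arrays 2 and 3. Without capped values it was 0.71 and 0.69, against 0.71 and 0.77. The block's added calls therefore cannot be read as an allowance for RNA shared within a pair. The share lower was 52.0% with array weights and 57.2% without capped probes. Arrays 1 and 2 and arrays 3 and 4 averaged first gave 123 lower and 21 higher (85.4% lower). Trended and robust moderation, whose trend ran over the ratio under test, gave 311 lower and 0 higher. In that fit 1278 genes were higher at an unadjusted p under 0.05 by limma. Leaving out arrays 1, 2, 3 and 4 in turn gave 192, 159, 178 and 190 genes lower and 43, 21, 19 and 33 higher, and with the arrays turned by the labels' channel order limma called 0 genes, with 18 at an unadjusted p under 0.05.

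**Figure D3:**
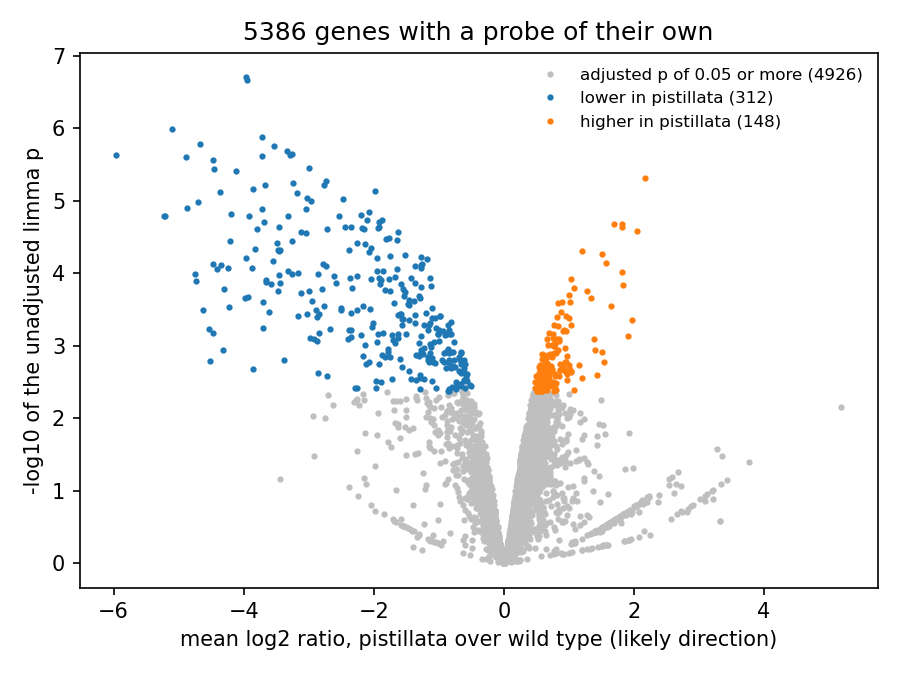
Mean log2 ratio of pistillata over wild type in the likely direction (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 5386 genes; each point is 1 gene, blue for the 312 lower, orange for the 148 higher and grey for the rest. Among called genes the lower ones extend further from 0, to -5.96, than the higher ones, to 2.17.

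The tapetum is the anther layer that feeds pollen and lays down its wall. All 3 measured genes of the tapetum list were lower in the likely direction. SWEET8 was at -3.71 ± 0.47, SHT at -3.66 ± 0.82 and ATA20 at -2.96 ± 0.74 (SD, n = 4 each; limma adjusted p = 0.00219, 0.006 and 0.00865). TUA1, the only member of the fixed pollen list with its own probe, was at -0.47 with an adjusted p of 0.102 by limma. These 4 genes set the sign of every array, so their common sign was built in and neither it nor the list's test is independent evidence. The tapetum list had a camera adjusted p of 2.33e-05 by limma, and it did not pass with the correlation between genes estimated (adjusted p = 0.0737 with an estimated correlation). By the labels' channel order its camera adjusted p was 0.78.

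Probes that list a member of a fixed list, alone or among several genes, widened the view, although a probe with several genes names none of them. With the probes of the 4 direction genes set aside, 15 of 16 probes for mature pollen and the pollen tube were lower, with a median log2 ratio of -3.04 (limma camera adjusted p = 1.65e-17; adjusted p = 0.216 with an estimated correlation). For the tapetum and pollen wall, 4 of 5 such probes were lower, with a median of -3.91 (camera adjusted p = 0.000138; adjusted p = 0.309 with an estimated correlation). Adjusted over the list alone, 16 of the 16 pollen probes and 5 of the 5 tapetum probes passed. Both lists were meant to fix the direction, so they do not test it. Turned by the labels' channel order, 0 of these 16 and 0 of these 5 probes passed limma's test, and 0 had an unadjusted p under 0.05.

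The petal and floral scent list was not used to set the direction. AT3G25810, a terpene synthase that the list holds as TPS24, was its only member with a probe of its own and was 13.8-fold lower in pistillata, at -3.79 ± 0.57 (SD, n = 4; limma adjusted p = 0.00239). Over probes with 1 or several genes, 3 of 5 of that list were lower, and 3 were when adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.404 with an estimated correlation). By the labels' channel order 0 of the 5 passed limma's test and 0 had an unadjusted p under 0.05.

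The carpel is an organ that pistillata flowers still form. Of the 21 genes of the carpel and ovule list, only 1, INO, had a probe of its own, and it was not called. INO, a YABBY factor of the outer ovule integument measured by 3 probes, was at -0.20 ± 0.18 (SD, n = 4; limma adjusted p = 0.288). Of 9 probes for the list, 0 passed limma's test over all probes, 6 had an unadjusted p under 0.05 and 4 passed adjusted over the list alone. The median of the 9 was 0.44, where that of all probes was 0.14, and the camera adjusted p was 0.453. The floral organ identity list had 0 genes with a probe of their own. Its 4 probes shared with other genes had a median of 0.50, with 0 passing, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (limma camera adjusted p = 0.116; fry unadjusted p = 0.00731 against 0).

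Meiosis genes lay slightly above 0, with no gene called. RCK, a meiotic crossover helicase, was at 0.52 and SPO11-2, of the complex that cuts DNA in meiosis, at 0.60 (limma adjusted p = 0.108 for both). Of the 4 meiosis genes measured, 0 passed over all genes, 2 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone (median 0.41; camera adjusted p = 0.137). Limma's fry, which sets the members against 0 and not against other genes, gave them an unadjusted p of 0.0238 for a common direction, where the median of all genes was itself 0.16. Over 11 probes with 1 or several genes, 0 passed, 0 passed adjusted over the list alone and 3 had an unadjusted p under 0.05 (limma camera adjusted p = 0.0677). Early anther patterning was represented by SPL at -0.24 and EMS1 at 0.17, with limma adjusted p of 0.382 and 0.465, and 0 of its 4 probes passed, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.254).

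Photosynthesis genes showed no called change either. SBPASE, an enzyme of the Calvin cycle, was at 0.54 (limma adjusted p = 0.103), and of the 6 genes measured 0 passed, 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median 0.22; camera adjusted p = 0.453). Over 10 photosynthesis probes, 0 passed by limma and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.435). The flavonoid glycosyltransferase UGT78D1 was at 0.18 (limma adjusted p = 0.44), and of 2 flavonoid probes 0 passed over all probes and 1 adjusted over the list alone. The 2 reference genes measured, AT2G28390 and AT4G34270, were at 0.14 and 0.05 (limma adjusted p = 0.415 and 0.743), and 0 of 5 reference probes passed, with 1 at an unadjusted p under 0.05 and a camera adjusted p of 0.758. Cell division had 2 probes shared with other genes, 0 of them called and 0 at an unadjusted p under 0.05 by limma, and the stamen maturation and jasmonate list had 0 probes.

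MADS-box genes, the broad family that includes PISTILLATA, held 18 members with a probe of their own. No gene of the floral organ identity list was among them, so they do not speak for those regulators. None passed limma's test over all genes (0 of 18), 0 passed adjusted over the family alone, and 5 had an unadjusted p under 0.05. The family's median was 0.25, close to the median of all genes of 0.16, and camera gave an adjusted p of 0.383 (adjusted p = 0.418 with an estimated correlation). By limma's fry, a test against 0, the unadjusted p was 0.0283 for a common direction and 8.02e-05 for change in either direction. A small value of the latter was not particular to this family. It was 0.000174 by fry for 18 UGT glycosyltransferase genes with 1 called, though 0.317 for the photosynthesis genes. Among the MADS-box genes, AGL85 had 3 capped values and AGL76 had 1. The MADS-box family was the only planned family with at least 8 members, so its camera p was adjusted over 1 family. Words sought in symbols and synonyms found 0 lipid transfer and 0 GDSL genes, though genes of both families are named above. The family sizes therefore do not show which families the array held.

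Channel bias was measured as the part of the ratio that follows the channel and not the genotype. As the channels were ordered in the labels, a term for arrays 1 and 3 against 2 and 4 was called for 0 of 26156 probes by limma, with 429 at an unadjusted p under 0.05. With the order seen in the anther genes, arrays 1 and 4 against 2 and 3, the term was called for 89 probes, all with a positive sign, and 2100 probes had an unadjusted p under 0.05. With that term in the fit, 255 genes were lower and 86 higher, against 312 and 148 without it. At an unadjusted p under 0.05 by limma, 1163 genes were higher with the term and 1094 without it. The cause of the smaller counts was not tested.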

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

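The tests of the array order in this part were chosen only after the order had been seen.

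AT5G53710 had a log2 ratio of 2.31 on array 2, and the gap to its nearest neighbour was 0.941 of the range of its 4 values. It was the only such value among 24 sets of 4 values tested, and chance gives about 1 in 20.

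Empty spots, which carry no gene probe, reached the upper cap of the table on 48.6% of their values on array 2, 70.6% on array 3 and 57.2% on array 4. Gene probes of the main set did so on 2.58%, 2.81% and 1.83% of theirs. On array 1 the share was 9.67% of empty spots.

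The signs of the ratios did not follow the labels' channel order. If the ratios followed the labels' channel order, gene probes beyond 2-fold on all 4 arrays would have one sign on arrays 1 and 3 and the other on arrays 2 and 4, and 7 of 1406 (0.498%) did, against 1193 (84.9%) that set arrays 1 and 4 against arrays 2 and 3. Of 232 empty spots beyond 2-fold on arrays 2, 3 and 4, 7 (3.02%) had a sign on array 4 opposite to that on arrays 2 and 3. Most of those gene probes had such a sign. This share cannot decide on a bias of a channel. With 1 numerator throughout, such a bias would push every array the same way and could not give this order, whatever the empty spots showed. An exchange of the channel labels of a pair of arrays may account for the order, with a correlation of -0.68 between arrays 1 and 3 over probes with no capped value, and so may a numerator that changes between arrays 2 and 3. The empty spots count against a changed numerator, since 224 of the 232 (96.6%) had the same sign on arrays 2, 3 and 4, but only if they favour the same channel on every array, and on array 1 they reached the upper cap 35 times and the lower cap 19 times, so it stays open; the genotypes are on every array, and no biological explanation was tested.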

How the results depend on the processing

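Turning by the labels' channel order, leaving out capped probes, genes with 1 probe only and list probes with several genes were chosen after the data were examined. All counts are limma calls, and where a count moved the cause was not tested unless fewer arrays or a stricter threshold give it. The planned filter on dim probes was not run, and signal over background limits these ratios to an unknown extent.

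By the labels' channel order there were 0 genes lower and 0 higher, 0 lower and 0 higher at least 2-fold, 0 probes lower and 0 higher, 18 genes at an unadjusted p under 0.05, and 0 pollen, 0 tapetum and 0 petal list probes lower. The log2 ratios of AT3G01250, AT3G52620, SWEET9, AT4G00910, AT5G53710 and SWEET8 reversed there, to 0.048, 0.33, 0.038, -0.063, -0.15 and 0.16, and 13 other named genes lost their call. The tapetum list's adjusted p was 0.78 there and 0.0737 with an estimated correlation, and 1.22e-05 to 5.03e-05 with an array left out.

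Centring gave 77 genes and 374 probes higher; 389 of its 427 called genes were among the 460 reported, and 0 of the 460 changed sign. Centring and scaling gave 89 genes higher, 18 of at least 2-fold, and 429 probes higher. The orientation term gave 86 genes and 477 probes higher, with 255 genes and 1556 probes lower. Trended and robust moderation gave 0 genes higher, 0 of at least 2-fold and 14 probes higher, with 1278 genes higher at an unadjusted p under 0.05. Its trend ran over the mean log ratio under test, so these counts cannot decide how many genes were higher. Array weights gave 365 genes higher and 395 lower, with 1784 probes higher and 2365 lower. The random block gave more higher than lower calls, 601 genes higher and 446 lower, with 2626 probes higher and 2598 lower. Leaving out capped probes gave 415 genes lower and 311 higher, 46 of at least 2-fold, and 1399 probes higher. Averaging arrays 1 and 2 and arrays 3 and 4 left 123 genes lower, 123 of at least 2-fold, and 21 higher, with 778 probes lower and 94 higher. An adjusted p of 0.01 left 145 genes lower, 145 of at least 2-fold, 19 higher and 16 of at least 2-fold, with 956 probes lower and 70 higher.

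With an array left out, genes lower ranged from 159 (array 2) to 192 (array 1), genes higher from 19 (array 3) to 43 (array 1), genes lower at least 2-fold from 159 to 186, genes higher at least 2-fold from 19 to 33, probes lower from 1046 to 1306 and probes higher from 85 to 190. Lower pollen list probes ranged from 11 to 13. All 20 named genes kept their side of the threshold and direction under centring, scaling, the orientation term, the removal of capped probes and without array 1; 2 lost the call without array 2, 2 without array 3 and 1 without array 4. Of the 11 lower and 8 higher named genes, 11 and 0 passed with trended and robust moderation, 10 and 6 with pairs averaged, and 11 and 6 at an adjusted p of 0.01. The meiosis and photosynthesis lists and the MADS family stayed above the threshold in camera under each alternative run on them, while fry, a test against 0, gave unadjusted p of 0.0238, 0.369 and 0.0283.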

Other observations

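The symbol, small-family and probe-set results in this part, and the tests of the lower and higher counts, were chosen only after the results were seen; the tests of neighbouring genes and of the sign patterns were planned before theirs.

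Of 5 expansins, proteins that loosen the cell wall, 3 were lower in pistillata by limma: EXPA24 at -4.48 ± 1.45 with 1 capped value, EXPB5 at -2.61 ± 0.53 and EXPA21 at -0.86 ± 0.37 (SD, n = 4 each; limma adjusted p = 0.0163, 0.00542 and 0.0498). EXPA20 and EXLB1 were at 0.71 and 0.36 without passing, and as a family the expansins missed the threshold (limma camera adjusted p = 0.0967). The cellulase-family genes GH9A4, with 1 capped value, and GH9B11 were at -4.32 ± 1.57 and -3.04 ± 0.37, and the xyloglucan-modifying enzyme XTH19 at -2.07 ± 0.80 (SD, n = 4 each; limma adjusted p = 0.0227, 0.00219 and 0.0286). The 9 genes with GH symbols, which also take in the auxin-conjugating enzymes GH3.1, GH3.3 and GH3.9 and so do not test cellulases alone, and the 5 xyloglucan genes missed the threshold as groups (limma camera adjusted p = 0.096 and 0.106). Of 10 serine carboxypeptidase-like genes, 3 were lower and SCPL43 was higher (camera adjusted p = 0.096).

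Other called genes were picked by name after their values were seen. RALFL25, a peptide of the rapid alkalinization factor family, was 15.6-fold lower at -3.97 ± 0.08, and PLIM2b, an actin-binding LIM protein of pollen, was at -1.77 ± 0.33 (SD, n = 4 each; limma adjusted p = 0.000585 and 0.00565). JMT, which makes methyl jasmonate, was at -2.74 ± 0.23 and the metal transporter gene NRAMP5 at -2.35 ± 0.64 (SD, n = 4 each; limma adjusted p = 0.00158 and 0.0112). Among higher genes were CES, a bHLH factor of brassinosteroid signalling, at 1.51 ± 0.52 and AGO7, an Argonaute protein of the trans-acting small RNA pathway, at 0.55 ± 0.09 (SD, n = 4 each; limma adjusted p = 0.0241 and 0.033). The UGT glycosyltransferases had 1 of 18 genes called, UGT73C1 at 0.94, and their median of 0.08 and mean of 0.0042 lay above 0 while camera placed them below other genes (adjusted p = 0.708). Of 3 histone genes 0 were called, with 2 at an unadjusted p under 0.05 (limma camera adjusted p = 0.154), and of 5 cytochrome P450 genes CYP71B26 was higher at 0.69 (camera adjusted p = 0.106).

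The additional probe set held a larger share of lower probes than the main set, 66 of 379 (17.4%) against 1824 of 25777 (7.08%), with an odds ratio of 2.77 and a p of 3.3e-11 by Fisher's exact test, two-sided. By the number in that set's probe identifiers, read as a plate, the share was 6.38%, 2.11%, 26.6% and 34.4% on plates 5, 6, 7 and 8. Plates 5 and 6 thus lay below the main set. Fisher's test takes single probes as independent, so its p does not measure a difference of the set as a whole.

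More genes were lower than higher at least 2-fold, 250 against 30. If values at the caps made it, the ratio would come near 1 once capped probes were left out, and it was 6.39, which argues against the caps as the whole cause. The centring of the arrays stays open: the ratio was 12.8 once each array was centred on its median, but all 4 turned medians lay above 0, so that step could only raise it. The loss of stamens and petals in pistillata stays open as a biological explanation and was not tested apart from the direction, which was itself set by anther genes.

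Genes lower in pistillata were tested for lying side by side on the chromosome. Of 1176 neighbouring pairs in which both genes were tested, 7 had both genes lower, against 3.94 on average in 10000 shuffles of the calls, and a share of 0.1 of the shuffles gave as many, so chance positions may account for the 7 pairs. Of the 7 pairs, 1 (14.3%) was listed together on a probe with several genes. Only genes with a probe that lists 1 gene were tested, which tends to leave out similar neighbours. That share therefore cannot decide on similar sequence, which stays open. For higher genes there were 3 pairs against 0.878, with a share of 0.057.

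The signs of the 4 arrays can be set in 8 ways, counting mirror images once. The order used gave 460 genes, 280 of at least 2-fold and 2669 probes. The highest of the other 7 orders gave 14, 14 and 54. In each case 1 order of 8, the one used, reached its count, and 8 orders are too few for a share under 0.05. The order used was itself set from these ratios, by the anther genes. Its larger counts were thus favoured in advance and are no independent evidence for it. For lists and families past the camera threshold, the order used gave 1 and the highest other gave 3, and 7 of the 8 orders gave as many as the order used, so chance could not be excluded there.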
